A study of Caenorhabditis elegans with 2 samples.

How the data were processed

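AMA-1 ChIP-seq peak lists from whole young adult worms (strain N2, mixed sex per the labels) were analysed, with 2 biological replicates in 1 group. Replicate numbers were taken from the labels. The labels give a size range without saying of what. The aligner, the peak caller and their versions are not given in the sources used here. Per the README deposited with each sample, each relaxed list was derived from alignments and a control alignment (replicate lists from 1 replicate, the pooled list from both), and the optimal IDR list from both replicates' relaxed lists and the pooled list. The control library itself was not used here. Peaks were therefore called per replicate and on pooled reads. The READMEs name 2 genome builds, ce10 and ce11, for the same data.

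The deposited peak signal value is a score made by the authors' peak caller, given in the column that the narrowPeak format reserves for it, and its scale differs between lists, so it was used only to rank peaks within a list. The deposited q-value column holds −log10 (q-value) in the narrowPeak format; all optimal peaks share the highest value in the pooled list, 4.05, as do 5554 of its 30000 peaks, so it could not rank them. The deposited summit offset, in bases from the peak start, gave the summit position. The optimal list on ce11 was found to be the 1103 strongest peaks of the pooled relaxed list by signal value. It has 1074 distinct intervals, since 45 entries share an interval with another entry and differ in summit; each entry was counted. Median widths were 336 bp in the pooled list, 304 bp in replicate 1 and 340 bp in replicate 2. Neither read totals nor any other depth can be read from the files used here, so the depth per sample is unknown, and intervals cover counting of genes or peaks only.

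Only ce11 lists were placed on genes, with the Ensembl release 115 annotation of WBcel235, which has the coordinates of ce11; all peaks ended within its chromosomes. Positions are 1-based. A gene held a summit that lay from 500 bp upstream of its annotated 5' end to its annotated 3' end, and a summit in several genes was counted for each and called ambiguous. Annotated 5' ends of trans-spliced worm genes are often the splice site rather than the start of transcription. Feature classes were given in the order promoter (500 bp upstream of a protein-coding gene), 5' UTR, 3' UTR, coding sequence, non-coding exon, intron, downstream (500 bp), intergenic.

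Tests fixed before the data were examined were Fisher's exact tests (feature classes, X against autosomes, centres against arms, 19 gene lists, 6 pairs of lists), an exact binomial test (gene ends, window 300 bp, genes of at least 2000 bp), and tests on the mean rank of signal values (exact under 10 values, otherwise 100000 resamples). All were two-sided with a threshold of 0.05 and Benjamini-Hochberg adjustment within each family. Gene lists were also set against 10000 random lists matched on length decile. The lists were cytosolic and mitochondrial ribosomal proteins, elongation factors, vitellogenins, intestine, body wall muscle, pharyngeal muscle, neurons, cuticle collagens, germline and oocyte, sperm, core histones, heat shock proteins, proteasome, oxidative phosphorylation, V-ATPase, glycolysis, RNA polymerase II subunits and chemoreceptors. Replicate overlap was set against 1000 random draws. Comparisons of replicates within gene lists, the test on SL2 RNA genes, and 2 further lists (moulting, starvation and dauer) were added after the data were seen.

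The genes named were, by a rule fixed beforehand, the 12 protein-coding genes with the strongest optimal summits (ties included), the 2 strongest members of each list and its first member without a summit, ama-1, and the strongest gene of each non-coding class. Genes named outside this rule are said to be chosen after their values were seen. Alternatives were a stricter list (551 peaks), a looser list (2206 pooled peaks), each replicate alone, gene bodies only, 1000 bp upstream, overlap of the peak with the gene body, only genes that overlap no other, other windows, other definitions of overlap, and build ce10.

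The tests were checked on simulated summits in 50 runs over 19973 genes. With no effect 0.421% of list tests were called, and the X test was called in 8% of runs. When 15 germline and oocyte genes were given summits, the list was called in 100% of runs, as was its difference between replicates when they were given in replicate 1 only. These planted effects were large, and the simulated replicates shared all their other summits, so both calls were near certain. How the replicate test behaves when replicates disagree at many genes, as the real ones did, was not simulated. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyfaidx 0.9.0.4 and matplotlib 3.10.9.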

Results

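The binding of AMA-1, the large subunit of RNA polymerase II, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult nematodes (Caenorhabditis elegans) of the laboratory wild type N2. The labels give 1 group with 2 biological replicates and no treatment, so no comparison between conditions was possible. What could be compared was where along the genome the polymerase peaks lay, which kinds of genes held them, and how far the replicates gave the same picture. The authors' final list, the optimal list of the irreproducible discovery rate (IDR) procedure, held 1103 peaks on genome build ce11. It was read against the longer relaxed lists of the pooled reads (30000 peaks), replicate 1 (27847 peaks) and replicate 2 (30000 peaks). The pooled relaxed list is labelled as peaks and background given to the IDR procedure. The −log10 (q-value) goes down to 0.639 in it, to 0.55 in replicate 1 and to 0.706 in replicate 2. A summit in a relaxed list may therefore lie in background rather than at bound polymerase. A peak carries the authors' signal value, used here only to rank peaks within a list. The number of reads behind each list is unknown, so intervals cover the counting of peaks and genes, and p-values of tests across genes or peaks describe these libraries rather than the spread between animals.

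The strongest polymerase peaks lay at genes of SL2 RNA, the small spliced leader that is joined to downstream messages of worm operons. The 3 highest signal values in the optimal list, 486, 479 and 477, were those of peaks at sls-2.1 (WBGene00004833), sls-2.4 (WBGene00004836) and sls-2.2 (WBGene00004834). Of 18 SL2 RNA genes, 12 (66.7%) had an optimal summit within 100 bp, against 8 of 99 (8.08%) other small nuclear RNA genes outside the SL1 family (Fisher's exact test, two-sided, p = 1.95e-07, chosen after the values were seen). None of the 12 annotated SL1 RNA genes had one, and none had a summit in the pooled relaxed list either. Whether reads could be placed uniquely at SL1 RNA genes was not checked, so this absence does not show that the polymerase was missing there. The gene sls-2.1 lies on chromosome II from 5844865 to 5844974 on the plus strand, and the summit of its peak (5844736 to 5845211) was at 5844965, inside the non-coding exon and 100 bp from the 5' end. On the reference genome this gene reads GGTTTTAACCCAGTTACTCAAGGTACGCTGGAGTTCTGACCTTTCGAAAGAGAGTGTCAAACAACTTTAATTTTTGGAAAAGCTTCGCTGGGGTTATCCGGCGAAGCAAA. The summit at sls-2.4 (chromosome I, 4172206 to 4172315, plus strand) was at 4172341, past the annotated 3' end. At sls-2.2 (chromosome II, 5543598 to 5543707, plus strand) the summit was at 5543697, and the neighbouring gene sls-2.3 (5544164 to 5544273, minus strand) held a separate peak with a signal value of 192. These 3 strongest peaks ranked 6, 3 and 4 in replicate 1 and 1, 3 and 2 in replicate 2.

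**Figure D1:**
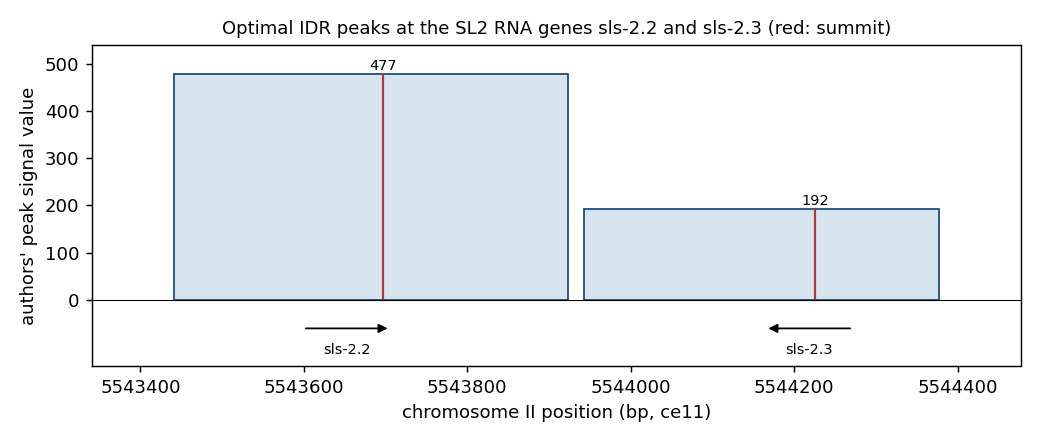
Optimal IDR peaks at a pair of SL2 RNA genes on chromosome II. The horizontal axis is the ce11 position in bp, the height of each box is the authors' peak signal value, the red line is the summit and the arrows are the genes in their direction of transcription; the peak at sls-2.2 reaches 477 and that at sls-2.3 reaches 192.

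Among protein-coding genes the strongest summits lay at mdt-26, F58G1.7, the overlapping pair T28F4.4 and T28F4.5, ift-43, tos-1, F01D5.10, drap-1, lgg-1, ego-1, M01H9.3, and the pair tim-1 and Y75B8A.23. The summit at mdt-26 (WBGene00016115), which encodes a Mediator subunit, lay in an intron on chromosome II at 5661804, 623 bp from the 5' end, with a signal value of 341. A second peak in the same region, at 5661274 with a signal value of 289, lay upstream of ift-43 and within the body of mdt-26, so its gene is ambiguous. The summit in the coding sequence of F58G1.7 (chromosome II, 12944744, signal value 330) lay close to sup-6, a small nuclear RNA gene inside it. The peak at the start of tos-1 (chromosome V, 9344149, 5' UTR) had a signal value of 266. At lgg-1, which encodes an autophagy protein, the summit lay in coding sequence (chromosome II, 6347505, signal value 188). The summit shared by tim-1 and Y75B8A.23 (chromosome III, 12250559, signal value 175) lay at sls-2.8 as well, so neither protein-coding gene can be singled out. Of the summits in the optimal list, 815 fell in a protein-coding gene or its 500 bp upstream, and 636 of 19973 protein-coding genes (3.18%) held at least 1. The gene of the precipitated protein itself, ama-1, held no optimal summit; its strongest summit ranked 1827 in the pooled relaxed list.

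Non-coding genes other than SL2 RNA also held summits. At cel-mir-52, a microRNA gene on chromosome IV (14034008 to 14034107), the summit at 14033984 had a signal value of 321, the highest of the microRNA class. It lay -24 bp from the 5' end, outside the microRNA gene, and near several other non-coding RNA genes, so its gene is ambiguous. Optimal summits were held by 22 of 261 microRNA genes (8.43%, 95% Wilson interval 5.63 to 12.4), 29 of 346 small nucleolar RNA genes (8.38%, 5.90 to 11.8), 8 of 612 tRNA genes (1.31%, 0.664 to 2.56), 10 of 194 long intergenic non-coding RNA genes (5.15%, 2.82 to 9.23), 4 of 2128 pseudogenes and 24 of 15363 piRNA genes. None of 20 ribosomal RNA genes held one. In the SL RNA class, SL1 and SL2 together, 8 of 30 genes did (26.7%, 14.2 to 44.45). Of the other small nuclear RNA genes, 3 of 99 did (3.03%, 1.04 to 8.53). These counts allow no distance past the 3' end, unlike the 100 bp used for SL2 RNA genes above. They do allow 500 bp upstream, so a summit counted here may lie outside the non-coding gene or at another gene. The strongest of the small nucleolar RNA class was W06H8.17 (signal value 170), of the long intergenic class K07C10.8 (78.9) and of the tRNA class WBGene00009555 on chromosome X (101.5), inside an intron of nhr-17. In the piRNA class the strongest was 21ur-14981, whose summit is the one upstream of ego-1. The summits of W06H8.17 and K07C10.8 lay at other annotated genes as well and are ambiguous too. The strongest pseudogene was WBGene00005825 on chromosome V (90.6).

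Optimal summits lay more often within 500 bp upstream or downstream of protein-coding genes, and less often in introns, than the other peaks of the pooled relaxed list. The upstream class was given first, and 35 of its 200 optimal summits (17.5%) lay inside the body of a protein-coding gene, as at hsp-110 and snb-1. Introns held 15.5% of 1103 optimal summits against 31.1% of the 28616 pooled relaxed peaks that overlapped none of them, with an odds ratio of 0.406 (Fisher's exact test, adjusted p = 1.14e-30). The 500 bp past 3' ends held 10.2% against 4.17% (odds ratio 2.62, exact test, adjusted p = 1.98e-16), and the 500 bp upstream of 5' ends 18.1% against 12.56% (odds ratio 1.54, adjusted p = 4.66e-07). Non-coding exons (4.99% against 2.097%), 5' UTRs (5.53% against 2.79%) and coding sequence (29.8% against 26.7%, exact test, adjusted p = 0.0279) were higher too, and intergenic sequence (11.6% against 15.7%) was lower. The share in 3' UTRs, 4.17% against 4.87%, was not past the threshold (exact test, adjusted p = 0.317). These were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 8 classes, and the call for coding sequence ended with only the stronger part of the list (adjusted p = 0.0594), with a list of 2206 pooled peaks (0.264) or with replicate 2 alone (0.0882); the call for intergenic sequence ended with windows of 250 bp (0.0558).

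**Figure D2:**
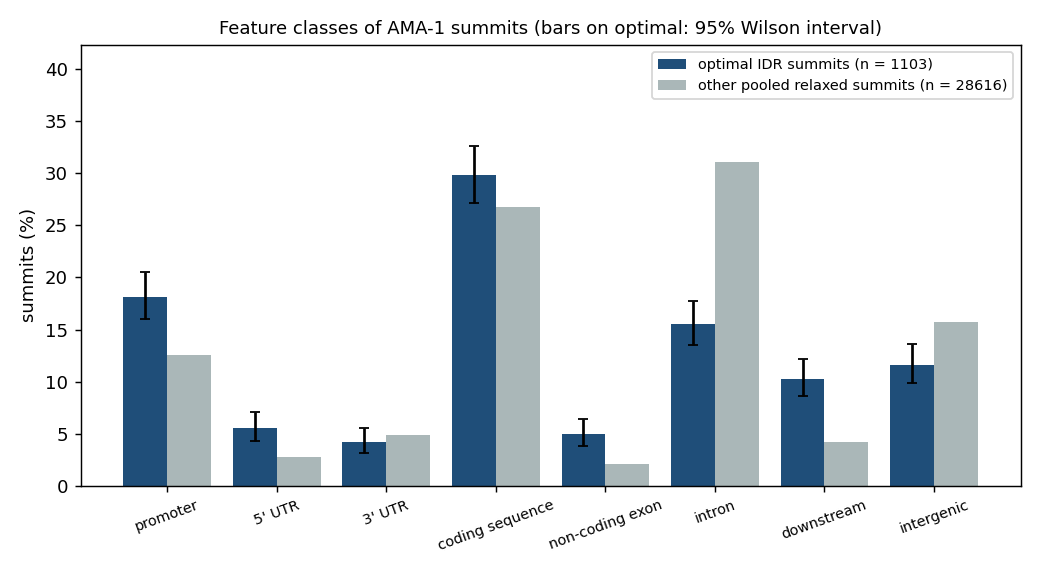
Share of AMA-1 summits in each annotated class, in percent, for the 1103 optimal IDR summits (dark bars, with 95% Wilson intervals) and the 28616 pooled relaxed peaks that overlap none of them (grey bars). Introns hold 15.5% of the optimal summits and 31.1% of the others, and the regions past 3' ends 10.2% and 4.17%.

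Along genes of at least 2000 bp, summits were not shown to favour either end. Within 300 bp of one kind of end of these genes only, 125 summits lay at a 5' end and 155 at a 3' end. Thus 44.6% (95% Wilson interval 38.9 to 50.5) were at 5' ends (exact binomial test against 0.5, two-sided, p = 0.0829). The share turned to 51.7% with a window of 150 bp (exact p = 0.711) and to 51.9% with 2206 pooled peaks (p = 0.381). Ends of shorter genes were not considered, so some of these summits may also lie near the other kind of end of a shorter neighbour. The split therefore does not settle where along genes the polymerase lay.

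Genes in the centres of autosomes held summits more often than genes on their arms, and genes on X less often than genes on autosomes. In the central 40% of the chromosomes 341 of 9008 genes (3.79%) held an optimal summit, against 295 of 10965 (2.69%) in the outer parts (odds ratio 1.42, Fisher's exact test, two-sided, p = 1.41e-05). On autosomes alone the shares were 4.05% and 2.74% (odds ratio 1.501, exact p = 2.11e-06). On X they went the other way, 24 of 1189 (2.02%) and 37 of 1542 (2.40%), with an odds ratio of 0.838 that was not past the threshold (exact p = 0.518), and the difference between X and autosomes was not tested. On X, 61 of 2731 genes (2.23%) held an optimal summit, against 575 of 17242 autosomal genes (3.33%), an odds ratio of 0.662 (Fisher's exact test, two-sided, p = 0.00184). The worm germline keeps X largely silent, but whether this lies behind the difference was not tested. With replicate 1 alone the odds ratio was 0.573, and 7 of the 46 germline and oocyte genes held a summit there. With replicate 2 alone the odds ratio was 0.699, and 0 of the 46 did. In the 27847 strongest peaks of replicate 1, 35.0% of X genes held a summit and 44.7% of autosomal genes. In those of replicate 2 the shares were 35.3% and 34.6%. The call for X ended when gene bodies alone were used (odds ratio 0.831, exact p = 0.240) and among genes that overlap no other (0.830, p = 0.427).

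Genes of heat shock proteins, glycolysis, translation elongation factors and cytosolic ribosomal proteins held optimal summits more often than other protein-coding genes, and chemoreceptor genes less often. Of 19 gene lists, 5 passed the threshold (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists). Heat shock proteins held summits in 9 of 21 members (42.9%, 95% Wilson interval 24.5 to 63.4, odds ratio 23.1, exact test, adjusted p = 6.31e-08), led by hsp-110 (signal value 85.7) and hsp-1 (78.0), while hsp-4 held none. Of the 2 genes for the BiP chaperone of the endoplasmic reticulum, hsp-4 is one, and the other, hsp-3, named after its value was seen, held a summit (47.2). The summit of hsp-110 also lay upstream of ufbp-1. Glycolysis genes held them in 5 of 19 (26.3%, 11.8 to 48.8, exact test, adjusted p = 0.00123), led by gpd-3, a glyceraldehyde-3-phosphate dehydrogenase (65.5), and enol-1, enolase (56.9), with none at hxk-2. Translation elongation factors held them in 3 of 6 (adjusted p = 0.00227 by the exact test), led by eef-1A.1 (57.2) and eef-2 (47.6), both ambiguous with a neighbouring gene; eef-1A.2 held none. Cytosolic ribosomal protein genes held them in 10 of 79 (12.7%, 7.02 to 21.8, odds ratio 4.46, exact test, adjusted p = 0.00123), led by rpl-1 (55.6) and rpl-15 (53.4), with none at rla-0. Chemoreceptor genes, most of which are active in few sensory neurons, held them in 3 of 1299 (0.231%, 0.0786 to 0.677, odds ratio 0.0660, exact test, adjusted p = 8.59e-14), with srh-2 (83.9) and srh-269 (75.2) the strongest and none at sra-1. The summit of srh-269 lay outside that gene, at -379 bp from its 5' end. That of srh-2 (chromosome V, 728984) lay in an intron, close to icl-1 (724332 to 728004, minus strand), a gene named after its value was seen. All 5 lists were also past the threshold against random lists matched on gene length, with adjusted p from 0.00127 to 0.0038.

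The calls for the ribosomal proteins and elongation factors depended on how summits were tied to genes, on replicate 1 and on the length of the list. Both calls ended in some settings and held in others. Heat shock proteins, glycolysis and chemoreceptors stayed past the threshold with replicate 2 alone (odds ratios 14.9, 13.7 and 0.0425, exact test, adjusted p = 2.95e-05, 1.46e-04 and 1.46e-15). They also did with the stronger part of the list (adjusted p = 0.00329, 0.0223 and 1.50e-05, exact tests), with gene bodies alone and by peak overlap. The summits of rpl-1 and rpl-15 lay outside these genes, at -471 bp and -336 bp from their 5' ends, and in the window of a neighbouring gene as well. In replicates 1 and 2, rpl-1 ranked 246 and 21376, and rpl-15 ranked 935 and 673. With gene bodies alone the odds ratio of the cytosolic ribosomal proteins was 0.550 (exact test, adjusted p = 1), and with replicate 2 alone it was 2.43 (adjusted p = 0.123). The call for the elongation factors ended with gene bodies alone (exact test, adjusted p = 0.408) and with replicate 2 alone (0.0703). With the stronger part of the optimal list, 551 peaks, both calls ended (odds ratio 2.37, adjusted p = 0.448 for the ribosomal proteins and 11.97, 0.361 for the elongation factors, exact tests). They also ended when peaks had to overlap the gene body (1.199, adjusted p = 0.783, and 15.2, 0.0532, exact tests). Both calls held with the looser list (7.07, adjusted p = 5.60e-11, and 15.04, 0.01145, exact tests). They held with 1000 bp upstream as well (4.32, adjusted p = 6.36e-04, and 26.5, 0.00339, exact tests). With replicate 1 alone the odds ratios were 7.226 and 30.35. The median length was 754 bp in the cytosolic ribosomal list and 2027 bp over protein-coding genes. Whether short bodies lowered its gene-body odds ratio was not tested. Among the 7678 genes that overlap no other, only the chemoreceptors stayed past the threshold (exact test, adjusted p = 6.68e-05). Few members of most other lists remained, apart from 65 cuticle collagens and 32 sperm genes. There the 6 heat shock proteins had an odds ratio of 23.6 (exact test, adjusted p = 0.0589), the 4 glycolysis genes 15.65 (0.319) and the 10 cytosolic ribosomal proteins 5.21 (0.454), each at least as large as among all genes.

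The other 14 lists were not past the threshold in the optimal list, but several passed it under other settings. Core histones held summits in 5 of 50 (exact test, adjusted p = 0.0665), led by the shared summit of his-35 and his-41 (83.7), with none at his-1. This shared summit was counted for both genes, so the 5 members are not independent of each other. That list took every gene with a numbered his symbol, so it was not limited to core histones by function. Oxidative phosphorylation genes held summits in 4 of 37 (exact test, adjusted p = 0.0796), led by atp-1 (66.4) and ucr-11 (45.2), with none at asb-1. With 2206 pooled peaks the oxidative phosphorylation list passed the threshold (odds ratio 3.51, adjusted p = 0.0171), as did the V-ATPase (8.12, 5.23e-04), the proteasome (4.06, 0.0115), mitochondrial ribosomal proteins (2.38, 0.0400) and, with no summit, sperm genes (0.0204), all by the exact test. These 5 lists also passed with all pooled peaks at the highest −log10 (q-value), a setting chosen after the data were seen. Oxidative phosphorylation also passed with 1000 bp upstream and by overlap of the peak with the gene body (exact test, adjusted p = 0.0287 and 0.0289). Core histones passed with the stronger part of the list, with 1000 bp upstream and with replicate 1 alone (exact test, adjusted p = 0.0436, 0.0287 and 0.00275). Mitochondrial ribosomal proteins did in 5 of 66, led by mrpl-32 (45.6) and mrps-7 (44.9), with none at mrpl-1. The V-ATPase did in 2 of 20, vha-1 (53.9) and vha-11 (46.7), the proteasome in 2 of 33, rpn-8 (42.8) and rpt-2 (42.6), and RNA polymerase II subunits in 1 of 12, rpb-9 (43.1). The summits of mrps-7, rpn-8 and atp-1 also lay in the window of a neighbouring gene. Among tissue markers, body wall muscle held a summit in 1 of 25 (act-4, 81.7), neurons in 1 of 25 (snb-1, 43.3, ambiguous with syx-18), intestine in 1 of 22 (acdh-1, 58.6), vitellogenins in 1 of 6 (vit-6, 41.5) and pharyngeal muscle in 0 of 7. Of these genes, vit-6 ranked 153 in replicate 1 and had no summit in replicate 2, while act-4, snb-1 and acdh-1 had summits in both. Cuticle collagens held optimal summits in 2 of 175, col-103 (108) and col-42 (67.9). No summit was held by the 46 germline and oocyte genes (upper Wilson limit 7.71%) or by the 81 sperm genes (4.53%). Many of the sperm genes belong to the msp and nspd families, and whether reads could be placed uniquely there was not checked. Low counts of sperm genes may therefore not reflect a lack of polymerase. The first members without a summit were elt-2, myo-3, myo-1, rab-3, bli-1, glh-1, msp-3, vit-1, vha-2 and pas-1. None of the 6 tests between pairs of lists was past the threshold (Fisher's exact test, lowest unadjusted p = 0.323, 0 below 0.05), so no difference between these lists was shown in the optimal list. This turned on replicate 2: in the 1103 strongest peaks of replicate 1 alone, germline and oocyte genes stood 13.98 points above sperm genes and cytosolic 14.4 points above mitochondrial ribosomal proteins (exact test, adjusted p = 0.0206 and 0.0316). There the odds ratio of the germline and oocyte list itself was 5.47 (exact test, adjusted p = 0.00193), and the V-ATPase (7.59, 0.00798) and vitellogenins (15.15, 0.0298) passed as well. The ranks of the signal values did not set any of the 8 lists with 3 or more summits apart either (permutation or exact tests, lowest adjusted p = 0.0576, unadjusted p below 0.05 in cytosolic ribosomal proteins, 0.0141, and mitochondrial ribosomal proteins, 0.0144).

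**Figure D3:**
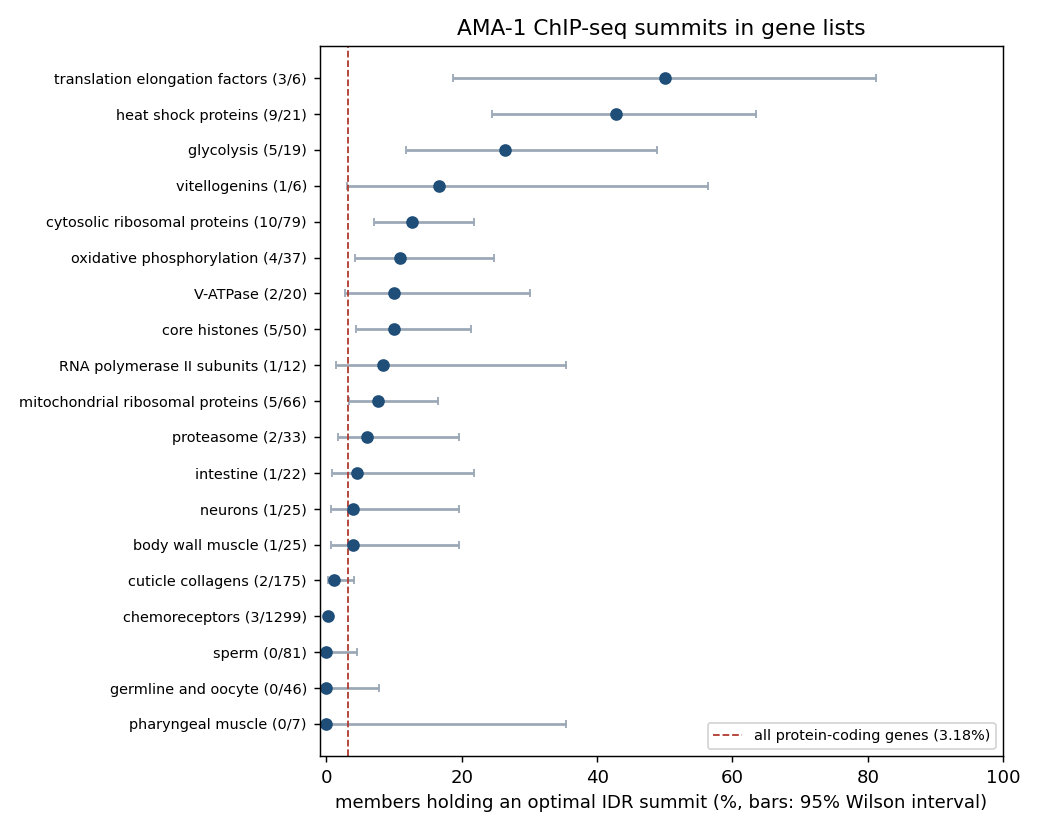
Share of the members of each gene list that hold an optimal IDR summit, in percent, with 95% Wilson intervals; the numbers in brackets are members with a summit over all members, and the dashed line is the 3.18% of all protein-coding genes. Elongation factors (3 of 6) and heat shock proteins (9 of 21) stand highest, and chemoreceptors (3 of 1299) lie below the line.

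The replicates shared their strongest peaks far more often than chance, although most were not shared, and the optimal list followed replicate 2 more closely. Of the 1103 strongest peaks of replicate 1, 463 (41.98%, 95% Wilson interval 39.1 to 44.9) overlapped one of the 1103 strongest of replicate 2, against a mean of 2.31% and a maximum of 3.99% in 1000 random draws. Among optimal peaks, 55.2% were overlapped by the 1103 strongest of replicate 1 and 79.4% by those of replicate 2; 152 were overlapped in replicate 1 only and 419 in replicate 2 only (exact binomial test, two-sided, p = 7.50e-30). Across the 1055 optimal peaks found in both relaxed lists, Spearman's rho between the replicates' signal values was 0.214, and it was 0.409 across the 460 peaks shared by the strongest 1103 of each. These are values across peaks, which are not independent replicates. Overlap fell to 26.3% when 50% reciprocal overlap was asked for and to 29.3% for summits within 100 bp.

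Germline and oocyte genes held summits in replicate 1 but mostly not in replicate 2. In lists of equal length, the 27847 strongest peaks of each replicate, 43 of these 46 genes (93.5%) held a summit in replicate 1 and 9 (19.6%) in replicate 2; 34 did in replicate 1 only and 0 in replicate 2 only (exact binomial test, two-sided, adjusted p = 2.21e-09 over 19 lists). Their lean to replicate 1 exceeded that of other genes held in a single replicate (Fisher's exact test, adjusted p = 1.03e-04). The germ granule helicase gene glh-1 (WBGene00001598) ranked 1725 in replicate 1 and had no summit in replicate 2. Chosen after their values were seen, pgl-3 (rank 167), csr-1 (325) and cpg-2 (920) also had a summit in replicate 1 and none in replicate 2, and the RNA-binding protein gene car-1 ranked 159 and 5055. Intestine genes (15 and 6 of 22), core histones (17 and 7 of 50) and chemoreceptors (65 and 34 of 1299) were also held more often in replicate 1 (adjusted p = 0.0247, 0.0302 and 0.00144 by the exact binomial test), but not beyond other genes (adjusted p = 0.415, 0.476 and 1 by Fisher's exact test). With gene bodies alone the calls for core histones and chemoreceptors ended (exact test, adjusted p = 0.231 and 0.155), and among genes that overlap no other those for intestine and core histones did (0.0990 and 1). Cuticle collagens went the other way relative to other genes, with 52 and 65 of 175 held, 30 in replicate 1 only and 43 in replicate 2 only (adjusted p = 3.29e-06 against other genes by Fisher's exact test, 0.427 for the collagens on their own). Among genes that overlap no other, 11 of them in the germline and oocyte list, the calls against other genes ended for that list (exact test, adjusted p = 0.102) and for the collagens (0.0620), with log2 odds ratios (0.5 added to each count) of 3.55 and -1.52 against 4.87 and -1.80 in the main setting. With the 1103 strongest peaks of each replicate they ended as well (exact test, adjusted p = 0.120 and 1, log2 odds ratios 4.01 and -0.30), and with the 5000 strongest both stayed past the threshold (1.00e-05 and 0.0457). These comparisons of 2 libraries were added after the data were seen.

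In the remaining lists the replicates were not shown to differ by the exact binomial test in the main setting. With gene bodies alone, cytosolic (62 and 37 of 79) and mitochondrial (52 and 36 of 66) ribosomal proteins were held more often in replicate 1 (exact test, adjusted p = 4.42e-05 and 0.00255), but not beyond other genes (Fisher's exact test, adjusted p = 0.101 and 0.309). Counts in replicates 1 and 2 were 21 and 22 of 25 for body wall muscle, 18 and 20 of 25 for neurons, 3 and 1 of 7 for pharyngeal muscle, 2 and 0 of 6 for vitellogenins, and 14 and 6 of 81 for sperm. They were 74 and 69 of 79 for cytosolic and 59 and 51 of 66 for mitochondrial ribosomal proteins, 19 and 18 of 21 for heat shock proteins, 33 and 32 of 33 for the proteasome, and 35 in both of 37 for oxidative phosphorylation. For the V-ATPase they were 18 in both of 20, for glycolysis 17 and 16 of 19, for RNA polymerase II subunits 11 and 8 of 12, and for elongation factors 6 in both of 6. Over all protein-coding genes 8657 (43.3%) held a summit in replicate 1 and 6925 (34.7%) in replicate 2. On X the shares were 35.0% and 35.3%, and on autosomes 44.7% and 34.6%.

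**Figure D4:**
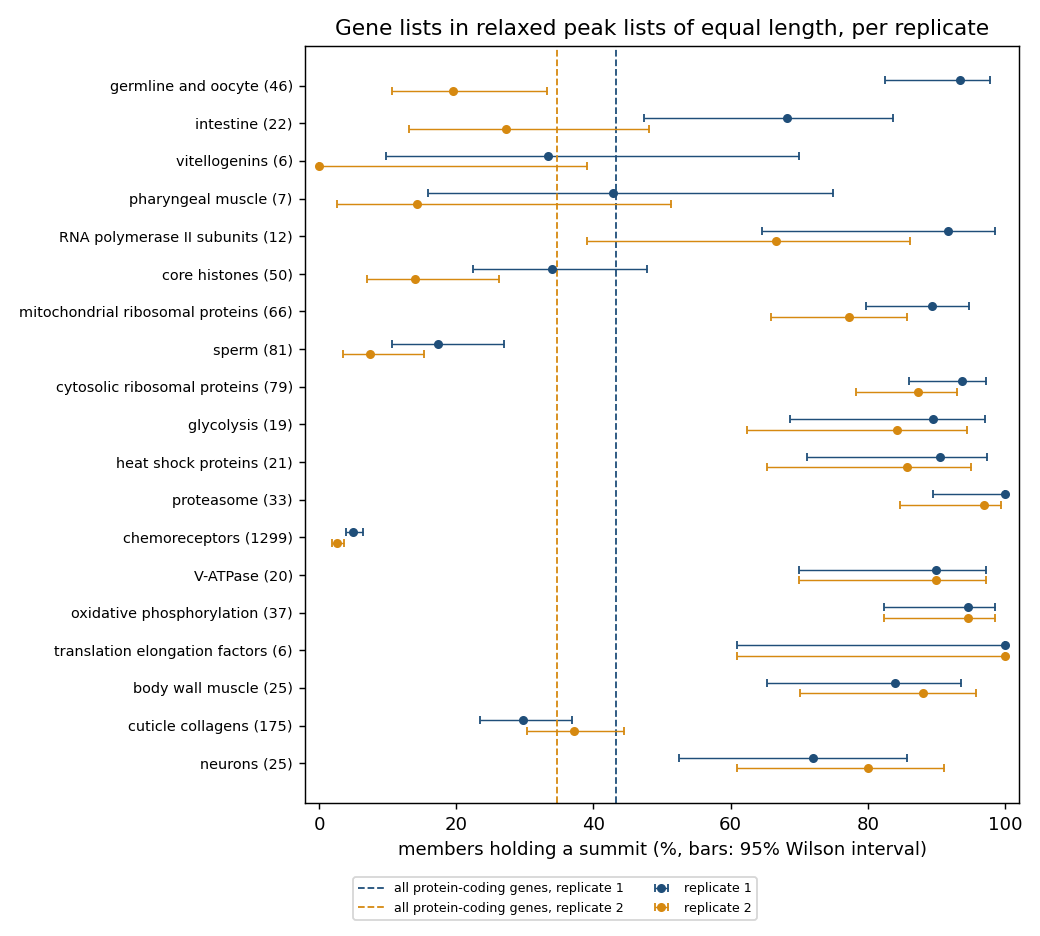
Share of each gene list's members that hold a summit among the 27847 strongest peaks of replicate 1 (blue) and of replicate 2 (orange), in percent, with 95% Wilson intervals and the number of members in brackets; dashed lines are all protein-coding genes. Germline and oocyte genes stand at 93.5% in replicate 1 and 19.6% in replicate 2, and oxidative phosphorylation genes at 94.6% in both.

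The authors provided the same kinds of list on an older genome build, ce10, with 1067 optimal peaks. Their shares per chromosome were close on both builds, for example 15.8% on ce10 and 15.4% on ce11 for chromosome I and 13.3% and 13.1% for X, where the 144 ce11 peaks made 8.13 per Mb, close to the 8.35 per Mb of chromosome IV, the lowest of the autosomes, with 15.2 per Mb on chromosome III the highest. No coordinate was carried between the builds.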

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

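Alternatives for the replicate comparison within gene lists, for signal ranks and SL2 RNA genes with a replicate left out, and the list of all pooled peaks at the highest −log10 (q-value) were chosen after seeing the data. No paired analysis was possible because there is 1 group. Chromosome centres kept their direction and their side of the threshold under all 8 alternatives, and the count of feature classes past it stayed within 6 to 7. The call for X ended with gene bodies only (odds ratio 0.831) and with genes that overlap no other (0.830), and held in the other 6. For gene ends the share at 5' ends turned to 51.9% with the looser list and 51.7% with a window of 150 bp, and no setting was past the threshold. Replicate overlap was 26.3% with 50% reciprocal overlap and 29.3% with summits within 100 bp. The cause was not tested in any of these.

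The number of gene lists past the threshold, 5 in the main setting, was 10 with the looser list and 10 with all peaks at the highest −log10 (q-value), 3 with gene bodies only, 4 with the stricter list, 4 by peak overlap, 1 with genes that overlap no other (fewer genes were tested), and 3 to 9 with a replicate left out. Pairs of lists past it were 0 in the main setting and 0 to 2 with a replicate left out. In replicate 1 alone these 2 were germline and oocyte above sperm and cytosolic above mitochondrial ribosomal proteins. The lists differing between replicates, 4 by the exact binomial test and 2 against other genes, were 1 and 2 with the 5000 strongest peaks, 0 and 0 with the 1103 strongest, 4 and 2 with gene bodies only (where core histones and chemoreceptors gave way to cytosolic and mitochondrial ribosomal proteins), and 2 and 0 with genes that overlap no other; germline and oocyte genes leaned to replicate 1 in all of them.

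Some lists turned direction. With a replicate left out, the odds ratio of germline and oocyte genes ranged from 0 to 5.47 (the latter in replicate 1 alone, Fisher's exact test, adjusted p = 0.00193), their difference from intestine from -4.545 to 10.7 points, and the odds ratio of 3' UTRs from 0.949 to 1.18. In the same way collagens ranged from 0.888 to 1.05, vitellogenins from 0 to 15.15, the proteasome from 0 to 1.90 and RNA polymerase II subunits from 0 to 2.68, and neurons stood at 0 in both. With all peaks at the highest −log10 (q-value), germline and oocyte stood at 1.32. With gene bodies only the cytosolic ribosomal proteins fell to 0.550, and their difference from the mitochondrial ones was -1.76 points, or -0.748 points by peak overlap. With the looser list intestine stood at 0.714 and neurons at 0.625, and matched on length neurons held 0.939 times the random mean. Collagens minus body wall muscle was 1.54 points among genes that overlap no other. The rest turned because their few summits dropped to 0: mitochondrial ribosomal proteins, vitellogenins, neurons, proteasome and RNA polymerase II subunits (stricter list); and mitochondrial ribosomal proteins, elongation factors, intestine, body wall muscle, neurons, proteasome and RNA polymerase II subunits (genes that overlap no other).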

Other observations

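All tests here were added after the peak lists had been examined, and those on genes of like rank, on autosomes against X and on peaks of fully unique sequence after the result each bears on had been seen.

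Several genes known from fasting or dauer worms had strong peaks in both replicates. Named after their values were seen, icl-1, a glyoxylate cycle enzyme gene, ranked 18 in replicate 1 and 121 in replicate 2, acs-2, a fatty acid activating enzyme gene, 48 and 62, adh-1 11 and 226, and the non-coding RNA gene tts-1 9 and 19. In the optimal list their signal values were 149, 142, 131 and 242. The long non-coding gene C30E1.9 on X held the strongest peak of replicate 1 and ranked 10 in replicate 2.

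Germline and oocyte genes held summits far more often in replicate 1 than in replicate 2. Weaker enrichment or lower depth in replicate 2 as the whole cause is argued against: of the 43 held in replicate 1, 9 (20.9%) were held in replicate 2, and 10000 draws of other genes of like rank in replicate 1 gave 32.8 on average and never fewer than 22. A lower germline share in replicate 2 may contribute: outside the germline list, genes held in replicate 1 only were autosomal more often than genes held in replicate 2 only, with an odds ratio of 2.91 (Fisher's exact test, p = 3.62e-32). Moulting larvae in replicate 2 are a candidate explanation too, since of 20 moulting genes 12, such as noah-1, noah-2 and mlt-11, were held in replicate 2 only and 1 in replicate 1 only (exact binomial test, p = 0.00342), and none of them is in another list. Stage differences or a mislabelled sample stay open, as the labels give both replicates as young adults and no biological explanation could be tested against a group.

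Starved animals as the source of the strong peaks at fasting genes cannot be told apart from chance: of 20 other starvation and dauer genes 2 (daf-16 and hlh-30, 10%) held an optimal summit, an odds ratio of 3.39 (Fisher's exact test, p = 0.132), and 2 of the 20 are also in other lists. In relaxed lists of equal length 14 were held in replicate 1 and 8 in replicate 2, with 6 in replicate 1 only and 0 in replicate 2 only (exact binomial test, p = 0.0312). Genes in general leaned the same way (2984 and 1252), and against other genes the starvation list did not pass the threshold (Fisher's exact test, p = 0.189).

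The strong peaks at SL2 RNA genes could come in part from reads shared between SL2 RNA copies, and this cannot be told apart from binding. Inside the 12 genes with an optimal summit 80.5% of the 36-base stretches are in no other SL2 RNA gene, between the bounds set beforehand, with 41.3% at sls-2.1, 53.3% at sls-2.2 and 78.7% at sls-2.4, but 100% at sls-2.5, sls-2.8, sls-2.14, sls-2.15, sls-2.16 and sls-2.18, where reads of that length inside the gene cannot be shared. Reads that match several places in the genome stay open with it: over the 12 whole peaks 90.3% of the stretches occur once, past a bound of 90% set beforehand, but unique flanks raise that share (85.9% over the peak at sls-2.1), so the bound was a poor one, which was seen only afterwards. As the source of every peak such reads are argued against, since at 4 of the 12 peaks (sls-2.8, sls-2.14, sls-2.15 and sls-2.16) all stretches occur once. This holds for reads of 36 bases or more, and the read length is not given in the sources used here.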
